A study of Mus musculus with 6 samples.

How the data were processed

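Mouse embryonic fibroblast cultures were profiled on Illumina bead arrays carrying 45281 probes each. There were 6 arrays, 3 from wild-type cultures and 3 from cultures lacking cyclophilin D (CypD), the mitochondrial peptidyl-prolyl isomerase encoded by Ppif. Per the labels, the cells came from embryos of C57BL/6 background, RNA was extracted from the cultures as total RNA, and biotin-labelled RNA was hybridised. Groups and the replicate letters A, B and C were taken from the labels. The labels do not say whether the letters mark separate embryos, litters or cultures, so every p-value measures only the spread between these arrays, which may be technical.

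The authors deposited 1 table of linear probe intensities per array, with no background correction visible in the values, and 1 table of processed intensities for the whole series. BeadStudio 3.0 was used, per the submitters' processing notes; other settings of the scan are not given in the sources used here. The deposited per-array files give only a probe identifier and an intensity, per the file headers, with no detection p-value, control probe, slide or scan date. Background signal and slide could therefore not be examined. The lowest deposited intensity lay between 118 and 139 on the 6 arrays.

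The deposited processed table was compared with the scanner values. Its linear intensities were 0.981 to 1.01 times the quantile-normalized scanner intensities. It listed 12534 probes. Each listed probe had a highest value over the 6 arrays at least 1.20 times its lowest, and a highest value of at least 273. Among 5489 unlisted probes with a highest normalized signal above 300, the ratio of highest to lowest reached at most 1.21. The listed probes were thus selected for variation over the arrays. Gene names were given only for listed probes. Of these, 10653 had 1 gene symbol, 5 had several and 1876 had none, and the last 2 kinds were not named. Current symbols were assigned to 10643 probes through Entrez identifiers in the RefSeq gene table of mouse assembly GRCm38.p6, which also gave the order of genes along chromosomes. The named probes covered 7606 genes. A gene without a listed probe has no value here, because it varied too little, was too dim, or had no probe, and which of these applies is not known.

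Intensities were background-corrected with the normexp method (offset 50), placed on the log2 scale and quantile-normalized in limma 3.58.1 under R 4.3.3. A design based on detection p-values had been fixed before the data were examined, together with this fallback for files without them. Probes with a mean log2 intensity above the 40th percentile were kept, which left 27168. Differences between groups were tested with limma (lmFit, and eBayes with an intensity trend). Adjusted p-values are Benjamini-Hochberg values over all probes kept, two-sided, and a probe was called changed at an adjusted p under 0.05. Fold changes are knockout over wild type, errors of log2 fold changes are standard errors from limma, and errors of group means are SDs over 3 arrays. The offset compresses the fold changes of dim probes. The number of arrays limits the precision.

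A gene was represented by its tested probe of highest mean intensity. Of 161 genes named by the rule, 62 had several tested probes, and in 15 of these some probes passed the test and others did not; in 0 of them did probes rise and fall. Gene lists were written before the data were examined, and a list with at least 5 tested members was tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over 24 lists. Camera with an estimated correlation and fry were run beside it. Fry's directional p asks whether a list's genes move one way on balance, and its mixed p whether they change either way; neither compares a list with other genes. Because named probes were selected for variation, lists were compared with other named genes only.

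The named genes were fixed by rule. They were Ppif, Nnt, Cxcl12, Cxcr4, Ccnd1 and Cdkn1a whatever their values, and the 12 largest rises and 12 largest falls among called genes with an assigned name and no overlap between the groups. From each list, up to 4 called members of lowest p and up to 2 members that did not pass, those of highest intensity, were added. Sex-linked genes were added as values per array. The genes around Ppif were compared with all other genes by Fisher's exact test, two-sided, over 100 protein-coding genes on each side. After the data had been seen, 5 more lists were written, for targets of NF-kB, retinoid metabolism, axon guidance, histones and lysosome, and the NF-kB list was also tested without members of the earlier lists.

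The procedure was tested on simulated data for the knockout against wild-type comparison, with 27170 probes fitted. In these data 200 probes were set to change, and a further list of 25 was shifted upward. Among changed probes that passed the filter, it recovered 95.2% of those changed 2-fold and 54.3% of those changed 1.41-fold. Changed probes that failed the filter were left out of these shares. Of its 125 calls 4% were false, with the shifted list counted as changed. The simulation changed far fewer probes than the 5423 called in the data, which makes its adjusted threshold stricter. Its spread was taken from intensities before normalization. These shares therefore check the procedure and do not give the recovery or the false share in the data. Alternatives covered the background correction, the normalization, the processed table, the filter on dim probes, the variance model, array weights, the replicate letters as a block, each array left out in turn, the probe per gene and the set test. A filter at the 70th percentile of intensity, and the use of all protein-coding genes as the denominator around Ppif, were added after the data had been seen.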

Results

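Gene expression was measured in cultured mouse embryonic fibroblasts, the mixed connective-tissue cells that grow out of a minced embryo, with 3 arrays from wild-type cells and 3 from CypD knockout cells. Cyclophilin D is a matrix protein of mitochondria that promotes opening of the permeability transition pore. The series concerns a role of cyclophilin D outside mitochondria in the cell cycle and in migration toward chemokines, per its title, and the design compares the genotypes. Median array signals were 251, 238 and 223 for wild type A, B and C, and 229, 226 and 229 for knockout A, B and C. Normalized log2 intensities correlated across probes at 0.994 to 0.996 within wild type, at 0.996 within knockout and at 0.982 to 0.984 between groups. The SD of the log2 difference between arrays was 0.184 to 0.241 within groups and 0.394 to 0.414 between them.

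Ppif, the targeted gene, fell in the knockout arrays but kept a bright signal. Its log2 intensity was 13.63 ± 0.067 in wild type (SD, n = 3) and 12.26 ± 0.086 in knockout (SD, n = 3), a log2 fold change of -1.37 ± 0.066 (SE, limma adjusted p = 2.96e-09), or 2.59-fold lower. Every knockout array lay below every wild-type array, with 12.25, 12.35 and 12.18 against 13.57, 13.70 and 13.62. The knockout signal still stood at the 93.6th percentile of all probes, against the 97.7th in wild type. Only 1 Ppif probe was named, and its place relative to the deleted part of the gene is not given in the sources used here; a probe outside that part checks nothing. Nnt, a mitochondrial transhydrogenase that differs between C57BL/6 substrains, was dim in both groups, with a log2 fold change of 0.10 ± 0.12 (adjusted p = 0.66).

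The knockout and wild-type cells differed in many genes, with similar numbers in each direction after quantile normalization. Median scaling instead called 2283 probes upward and 3119 downward. Among named genes, Spon2, a secreted matrix protein, rose from 7.56 ± 0.099 to 13.09 ± 0.054 (SD, n = 3 each), a measured 46.3-fold (log2 fold change 5.53 ± 0.08, adjusted p = 8.07e-14). Slco4a1, an organic anion transporter, fell from 11.18 ± 0.032 to 6.96 ± 0.084, a measured 18.7-fold (log2 fold change -4.22 ± 0.09, adjusted p = 9.74e-13). Its knockout signal was at the 43.2nd percentile and the wild-type signal of Spon2 at the 63.9th, where background is not separated from expression, so these folds and their rank among other large changes are uncertain. Of 27168 probes tested, 5423 changed, 2656 upward and 2767 downward, and 663 changed at least 2-fold. The 2-fold count depended on the background correction, with 452 without it and 453 from the 12534 probes of the processed table. The median size of a called change was 1.36-fold. At an unadjusted p under 0.05, 8086 probes of any size of change were counted. Counted by gene, 3319 of 7605 changed, 1660 upward and 1659 downward, and 462 of them at least 2-fold. Named probes were selected for variation and had a highest value of at least 273, and both can raise these shares. Of 10651 named probes 4484 were called, against 939 of 16517 unnamed probes. When only the 13585 probes above the 70th percentile of intensity were tested, 4741 were called. The parts of variation and brightness were not told apart.

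The 12 largest rises ran from 8.88-fold to 46.3-fold. The growth factor genes Ptn (pleiotrophin) and Hgf (hepatocyte growth factor) rose 12.2-fold (3.61 ± 0.08, adjusted p = 9.74e-13) and 10.6-fold (3.41 ± 0.17, adjusted p = 3.89e-09). Sfrp1, a secreted Wnt antagonist, rose 10.1-fold by its brightest probe (3.34 ± 0.14, adjusted p = 7.14e-10), while its other probe gave 0.37 (adjusted p = 0.0594). Rbm45, an RNA-binding protein, and Aqr, a helicase of the spliceosome, rose 15.3-fold and 14.6-fold, each by the only named probe. Mff, which recruits the fission machinery to the mitochondrial outer membrane, rose by 3.47 ± 0.10 on the log2 scale (adjusted p = 2.32e-11). Fez1, an adaptor of axonal transport, rose 15.1-fold, and the remaining 5 were Hoxd8, Zcchc18, Gsc, Amigo2 and Spon2. In 11 of the 12 the wild-type signal lay below the 70th percentile of all probes, where the offset compresses fold changes and background is not separated from expression.

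The 12 largest falls ran from 6.49-fold to 18.7-fold. The monocyte chemoattractants Ccl7 and Ccl2 were 9.87-fold and 9.43-fold lower in knockout, and Ppbp, a platelet chemokine precursor, was 6.49-fold lower. Ifi202b, an interferon-inducible DNA-binding protein with close relatives in its gene cluster, was 14.8-fold lower (-3.88 ± 0.11, adjusted p = 1.05e-11). The homeobox genes Hoxc10 and Hoxc9 were 15.9-fold and 8.54-fold lower. Adh7, an alcohol dehydrogenase that also oxidises retinol, was 12.7-fold lower (-3.67 ± 0.09, adjusted p = 4.81e-12). Hey1, a target of Notch, fell by 2.81 ± 0.09 on the log2 scale, and Stmn2, a microtubule regulator of neurons, was 6.91-fold lower. The forkhead gene Foxq1 was 8.15-fold lower and the pseudogene Gpr137b-ps, whose probe may also bind its parent gene, 11.5-fold lower. In 7 of these 12 the knockout signal lay below the 70th percentile of all probes, with the same limit.

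**Figure D1:**
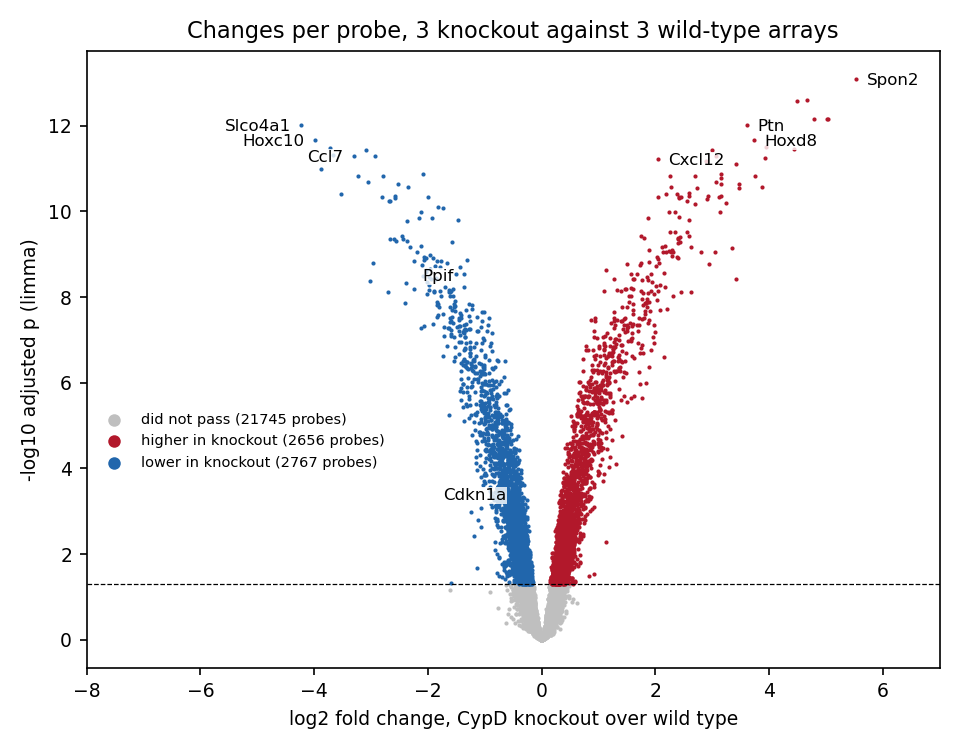
Each point is 1 of 27168 tested probes, with the log2 fold change of CypD knockout over wild type on the x axis and the -log10 of the limma adjusted p on the y axis; red points rose, blue points fell and grey points did not pass, and the dashed line marks the threshold. The 2656 rises and 2767 falls, from quantile-normalized values, form arms of similar size, with Spon2 at the upper right and Ppif among the falls.

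Chemokines, the secreted proteins that direct cell migration, changed in both directions in knockout cells. Cxcl12, the ligand of Cxcr4, rose 4.13-fold, from 13.57 ± 0.067 to 15.61 ± 0.037 (SD, n = 3 each; log2 fold change 2.05 ± 0.05, adjusted p = 5.94e-12), and its other probes gave 1.79 and 1.74. Ccl7 and Ccl2 had log2 fold changes of -3.30 ± 0.08 and -3.24 ± 0.09, and Ccl9 fell by 2.44 ± 0.10 (adjusted p = 4.43e-10). Of 12 tested members of the chemokine and receptor list, 4 rose, 8 fell and 0 did not pass, and 12 changed when adjusted over the list alone. The other members that rose were Cx3cl1, Ccl17 and Ccl27a, and the other members that fell were Ccl5, Cxcl1, Cxcl10, Cxcl16 and Ccl25, the last with another probe that did not pass (-0.24, adjusted p = 0.222). The list had a median log2 fold change of -1.02 (camera adjusted p = 0.036). This call was lost with an estimated correlation (adjusted p = 0.498), the probe of highest variance (adjusted p = 0.0596) and median scaling (adjusted p = 0.0601). A fit without the intensity trend (adjusted p = 0.0529) and a filter at the 70th percentile (adjusted p = 0.0914) ended it too. Cxcr4 itself was not among the named probes, and of the 43 list members 31 had no tested probe with a name.

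**Figure D2:**
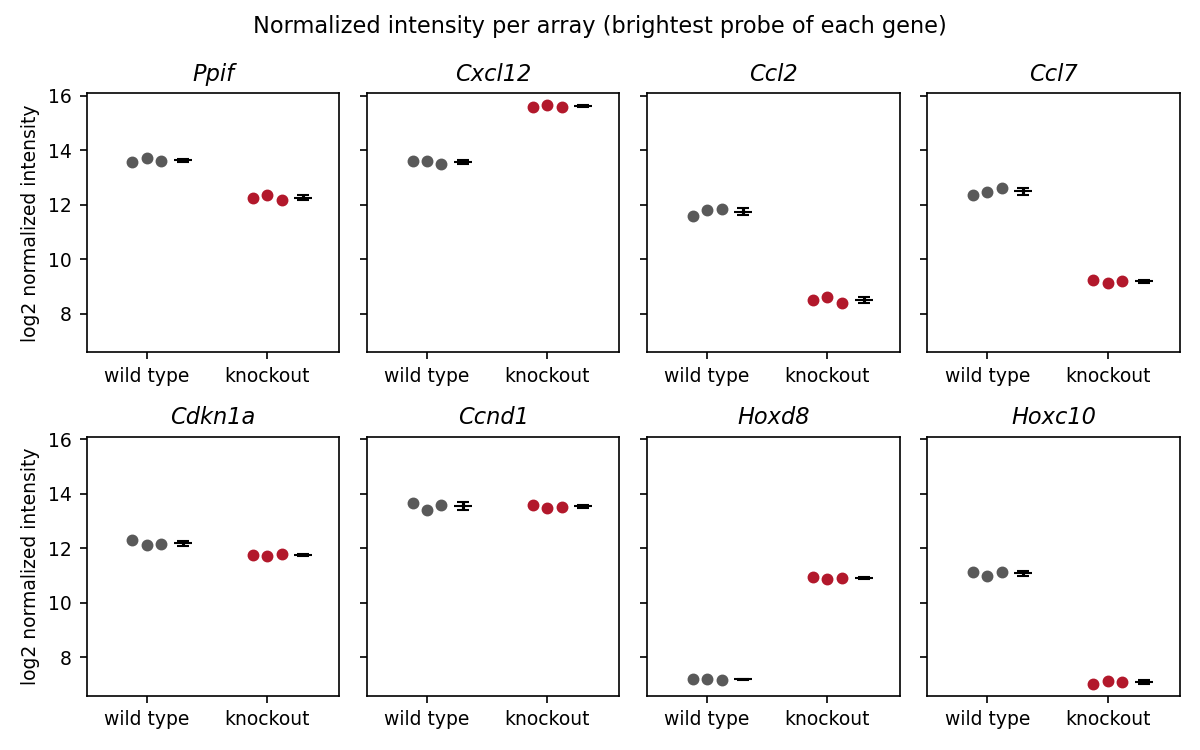
Points are normalized log2 intensities of the 3 wild-type (grey) and 3 knockout (red) arrays for 8 genes, each by its brightest probe, and bars give the mean ± SD of each group. The groups do not overlap for Ppif, Cxcl12, Ccl2, Ccl7, Cdkn1a, Hoxd8 and Hoxc10, while they overlap for Ccnd1 at 13.56 and 13.53.

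Most tested cell cycle genes did not pass, as held for tested genes of all kinds, of which 43.6% changed. Of the 36 members of each list below, 23 of replication and 20 of mitosis had a tested probe with a name. Pcna, the sliding clamp of DNA polymerase, rose 1.42-fold (0.50 ± 0.10, adjusted p = 0.00158), Gins2, a part of the replicative helicase, 1.27-fold and Rrm1, a subunit of ribonucleotide reductase, 1.21-fold, whereas Dut, which removes dUTP, fell by 0.50 ± 0.08 (adjusted p = 0.00033). A second Rrm1 probe did not pass (0.16, adjusted p = 0.132). Of 23 tested genes of DNA replication and S phase, 7 rose, 3 fell and 13 did not pass, and 11 changed when adjusted over the list alone. Tyms and Tk1, enzymes of thymidylate supply, had log2 fold changes of 0.16 ± 0.07 and -0.17 ± 0.10 and did not pass, though Tyms passed without wild type B (adjusted p = 0.0232) and Tk1 without wild type A (adjusted p = 0.0337). Of 20 tested genes of G2 and mitosis, 4 rose, 2 fell and 14 did not pass, and 8 changed when adjusted over the list alone. Nuf2, a kinetochore protein, fell by 0.64 ± 0.10, while the mitotic kinase Plk1 and the spindle factor Tpx2 rose by 0.22 ± 0.06 and 0.23 ± 0.06, calls that median scaling ended (adjusted p = 0.125 and 0.0909), as did a fit without the intensity trend (adjusted p = 0.088 and 0.082). The Plk1 call was also lost without knockout A (adjusted p = 0.0665), and the Tpx2 call without wild type A, knockout A or knockout C (adjusted p = 0.0935, 0.0761 and 0.0662). Kif23, a kinesin of cytokinesis, rose 2.20-fold by its brightest probe (1.14 ± 0.05, adjusted p = 2.33e-09), but its other probes gave 0.35, 0.16 and -0.07 and did not pass. Camera called neither list (adjusted p = 0.363 for replication and 0.371 for mitosis), while fry gave directional adjusted p = 0.0456 and 0.0319, both upward.

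Regulators of the G1 phase went in different directions. Cdkn1a, which encodes the CDK inhibitor p21, fell by 0.44 ± 0.07 (adjusted p = 0.000393), and its other probes had log2 fold changes of -0.61 and -0.39, the latter not called without knockout array C (adjusted p = 0.0801). The imprinted CDK inhibitor Cdkn1c rose 5.34-fold (2.42 ± 0.09, adjusted p = 1.35e-10) and Cdkn2d, another inhibitor, 1.56-fold. Fas, a death receptor and p53 target, fell by 1.17 ± 0.09 and the kinase Plk2 by 0.61 ± 0.07. Ccnd1, which encodes cyclin D1, had a log2 fold change of -0.03 ± 0.07 (adjusted p = 0.865), with 0.15 and 0.25 for its other probes, none of which passed. In the list of G1 cyclins, CDK inhibitors and p53 targets, 3 of 25 tested members rose, 6 fell and 16 did not pass (12 changed when adjusted over the list alone; camera adjusted p = 0.371).

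Matrix proteases, adhesion and contractile genes changed in mixed directions. Mmp2, a gelatinase, rose 4.78-fold (2.26 ± 0.06, adjusted p = 1.48e-11), while the stromelysin Mmp3, the collagenase Mmp13 and the protease inhibitor Timp3 were 5.29-fold, 3.14-fold and 3.56-fold lower. In the list of adhesion, motility and matrix proteases, 10 of 31 rose, 14 fell and 7 did not pass (24 changed when adjusted over the list alone; camera adjusted p = 0.371). The integrin subunit Itga3 and the adhesion molecule Ncam1 had log2 fold changes of 0.07 ± 0.07 and 0.07 ± 0.09 by their brightest probes, and another Ncam1 probe passed at 0.37. Among collagens and matrix genes, 5 of 24 rose, 10 fell and 9 did not pass (19 changed when adjusted over the list alone; camera adjusted p = 0.858). Col18a1, a basement membrane collagen, was 5.11-fold lower, and Vcan, Col3a1 and Ogn rose 2.38-fold, 2.19-fold and 2.11-fold. Of 13 tested contractile genes of smooth muscle and myofibroblasts, 2 rose, 7 fell and 4 did not pass (9 changed when adjusted over the list alone; camera adjusted p = 0.23). Myl9 and Tagln, which act on actomyosin in smooth muscle, were 4.12-fold and 2.03-fold lower, while the LIM protein gene Csrp1 and the stretch-responsive Ankrd1 rose 7.67-fold and 3.67-fold.

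Signalling genes of the growth factor, Wnt, TGF-beta and Notch pathways mostly changed, with more falls than rises. Of 38 tested members, 13 rose, 19 fell and 6 did not pass, and 34 changed when adjusted over the list alone (camera adjusted p = 0.262). Wnt5a, a noncanonical Wnt ligand, was 6.01-fold lower (-2.59 ± 0.08, adjusted p = 4.39e-11) and Pdgfb, a platelet-derived growth factor, 5.92-fold lower. In the list of STAT3 pathway genes and targets, 6 of 18 rose, 8 fell and 4 did not pass (17 changed when adjusted over the list alone; camera adjusted p = 0.918). The cytokine receptor subunits Il6st and Osmr rose 1.98-fold and 1.92-fold, and the cytokine Lif was 2.14-fold lower. Of 14 tested interferon-stimulated genes 1 rose, 10 fell and 3 did not pass, and 13 changed when adjusted over the list alone. The GTPase gene Gbp2 was 2.39-fold lower (-1.26 ± 0.09, adjusted p = 2.34e-07), and the antiviral genes Oasl2 and Isg15 were 1.67-fold and 1.61-fold lower, while Psmb9, an immunoproteasome subunit, rose by 0.48 ± 0.13. The list median was -0.45 (camera adjusted p = 0.0107), a call lost with an estimated correlation (adjusted p = 0.263 with an estimated correlation).

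Homeobox genes that mark positions along the body axis and limbs changed in both directions. Of 33 tested members of the list of Hox and other positional factors, 18 rose, 10 fell and 5 did not pass, and 28 changed when adjusted over the list alone (median 0.54, camera adjusted p = 0.153). Camera called the list among probes above the 70th percentile, a setting added after the data had been seen (adjusted p = 0.0132), while with an estimated correlation over all 33 tested members it did not (adjusted p = 0.547). Hoxd8 rose 13.3-fold, from 7.17 ± 0.019 to 10.91 ± 0.036 (SD, n = 3 each; adjusted p = 2.18e-12), and Meis2, a Hox cofactor, rose 5.35-fold. Hoxc10 was 15.9-fold lower, from 11.07 ± 0.086 to 7.08 ± 0.062 (adjusted p = 2.18e-12). Hoxc6 had a log2 fold change of -0.15 ± 0.10 and did not pass.

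Most tested imprinted genes, and most tested markers of cartilage, bone and fat, rose in the knockout cells. Dlk1, a preadipocyte factor that belongs to both lists, rose 8.02-fold, from 12.01 ± 0.15 to 15.02 ± 0.052 (SD, n = 3 each; adjusted p = 3.73e-12), and Ndn (necdin) and Mest rose 6.45-fold and 4.55-fold. Of 11 tested imprinted genes, 7 rose, 2 fell and 2 did not pass, and 10 changed when adjusted over the list alone (median 1.41, camera adjusted p = 0.000193, adjusted p = 0.255 with an estimated correlation). Col2a1, the cartilage collagen, rose 4.87-fold, the lipase Lpl 4.26-fold and Sox9, the master factor of cartilage, 2.14-fold. In that lineage list, 6 of 7 tested members rose, 0 fell and 1 did not pass, and 6 changed when adjusted over the list alone (median 1.10, camera adjusted p = 0.000188, adjusted p = 0.263 with an estimated correlation).

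Markers of other cell types moved in several directions, and few had a tested probe with a name. Of 5 neural and glial markers, 0 rose, 3 fell and 2 did not pass, and 4 changed when adjusted over the list alone (median -0.94, camera adjusted p = 0.0107, adjusted p = 0.295 with an estimated correlation). The falls were those of Stmn2, of the myelin gene Mbp and of the progenitor filament Nes. Among 7 endothelial markers 3 rose, 2 fell and 2 did not pass (6 changed when adjusted over the list alone; camera adjusted p = 0.89), with a median of -0.19 although the mean was 0.03 and the test pointed upward. Among 5 epithelial markers 1 rose, 1 fell and 3 did not pass (4 changed when adjusted over the list alone; camera adjusted p = 0.858). The rise was that of Spint1, whose other probe did not pass (0.23, adjusted p = 0.376), and the fall that of Krt19, a call lost without wild type A, knockout A or knockout C (adjusted p = 0.0581, 0.0788 and 0.0775). Of 2 tested leukocyte markers 0 passed, while 2 changed when adjusted over the list alone. Of these, Coro1a (0.30 ± 0.13) passed with array weights (adjusted p = 0.0392) and without wild type C (adjusted p = 0.00696), and Cd14 (-0.25 ± 0.09) without wild type B (adjusted p = 0.0462). Of 2 skeletal muscle markers Acta1 fell by 0.79 ± 0.12 and Myl4 did not pass (0.16 ± 0.11), and 1 changed when adjusted over the list alone. Of the erythroid list 0 members had such a probe. Xist, the X-inactivation transcript, had log2 intensities of 12.43, 12.59 and 12.51 in wild type A, B and C by its brightest probe. Its values in knockout A, B and C were 12.66, 12.70 and 11.87. Another bright Xist probe was also lowest in knockout C, with 11.55 against 12.65 and 12.46 in knockout A and B. The remaining, dim Xist probe was not, with 8.532 against 8.42 and 8.84. The Y-linked Uty was dim, with 8.09, 8.07 and 8.05 in wild type and 7.98, 7.69 and 7.79 in knockout. Kdm6a was dim too, with 7.476, 7.538 and 7.279 in wild type and 7.526, 7.721 and 7.505 in knockout. Eif2s3x on the X chromosome fell by 0.31 ± 0.07, a call lost without the intensity trend (adjusted p = 0.053).

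**Figure D3:**
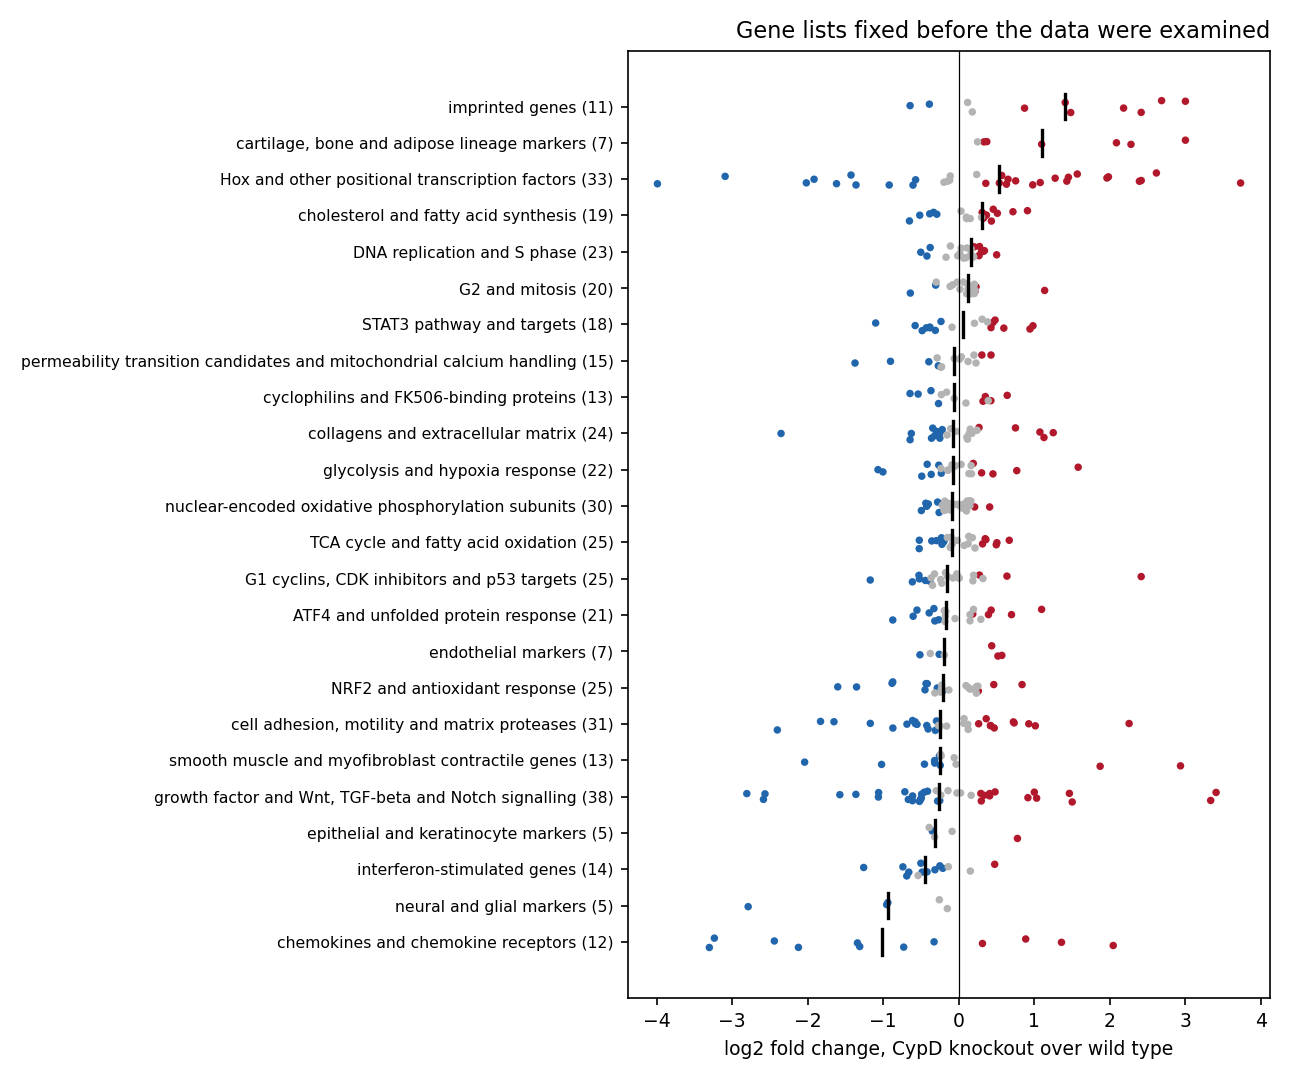
Each point is the log2 fold change of CypD knockout over wild type of 1 tested list member (x axis), red where it rose, blue where it fell and grey where it did not pass, and the black bar is the median of the list; numbers in parentheses count tested members. Medians run from -1.02 for chemokines to 1.41 for imprinted genes, with members on both sides in most lists.

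Most tested oxidative phosphorylation genes did not pass, while some other mitochondrial genes changed. Among tested genes of all kinds 43.6% were called. Tspo, an outer membrane protein once proposed as a pore component, was 2.59-fold lower (-1.37 ± 0.09, adjusted p = 6.96e-08), the inner membrane protease gene Afg3l2 1.87-fold lower and the chaperone gene Hspa9 1.32-fold lower, while Bcl2 rose 1.35-fold by its brightest probe. Of 5 Bcl2 probes 3 rose and 2 did not pass (0.26 and 0.31, adjusted p = 0.0683 and 0.121). In the list of permeability transition candidates and calcium handling, 2 of 15 rose, 4 fell and 9 did not pass (9 changed when adjusted over the list alone; camera adjusted p = 0.374). Vdac3, an outer membrane channel, had a log2 fold change of 0.12 ± 0.07 and did not pass. Of 30 tested oxidative phosphorylation subunits, 2 rose, 6 fell and 22 did not pass (10 changed when adjusted over the list alone; camera adjusted p = 0.371); Cyc1 of complex III fell by 0.49 ± 0.07. Among other cyclophilins and FK506-binding proteins, 4 of 13 rose, 4 fell and 5 did not pass (9 changed when adjusted over the list alone; camera adjusted p = 0.89). Ppic, a cyclophilin of the secretory pathway, was 1.56-fold lower, and Fkbp14 rose 1.56-fold. In the TCA cycle and fatty acid oxidation list, 6 of 25 rose, 8 fell and 11 did not pass (17 changed when adjusted over the list alone; camera adjusted p = 0.945). Its median was -0.09, its mean 0.01 and the direction of fry upward against downward for camera. Idh1 and Idh2, the isocitrate dehydrogenases that use NADP, rose 1.59-fold and 1.41-fold.

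Metabolic and stress genes showed scattered changes. In the glycolysis and hypoxia list, 5 of 22 rose, 7 fell and 10 did not pass (13 changed when adjusted over the list alone; camera adjusted p = 0.742); the glucose transporter Slc2a3 rose by 1.58 ± 0.12 and Ndrg1 was 2.10-fold lower. Gapdh, often used as a reference gene, had a log2 fold change of 0.17 ± 0.06 and did not pass, though it passed with array weights (adjusted p = 0.0308) and without wild type C (adjusted p = 0.0144). Among genes of ATF4 and the unfolded protein response, 5 of 21 rose, 7 fell and 9 did not pass (14 changed when adjusted over the list alone; camera adjusted p = 0.858). The transcription factor genes Atf4 and Xbp1 rose 2.14-fold and 1.62-fold, while Atf5 and the cystine transporter Slc7a11, a target of ATF4, were 1.52-fold and 1.83-fold lower; the other Slc7a11 probe did not pass (-0.24, adjusted p = 0.16). For NRF2 and the antioxidant response, 3 of 25 rose, 10 fell and 12 did not pass (18 changed when adjusted over the list alone; camera adjusted p = 0.371). Gsta1 and Gsta2, glutathione transferases whose near-identical sequences the probes may share, were 2.56-fold and 1.85-fold lower, and Gstm2 rose 1.79-fold. In cholesterol and fatty acid synthesis, 9 of 19 rose, 5 fell and 5 did not pass (15 changed when adjusted over the list alone; camera adjusted p = 0.23). Insig1, a sterol sensor partner, rose 1.88-fold and the desaturase Scd2 1.65-fold. Over all 24 lists tested, camera called 5, of which 2 were upward, and with an estimated correlation it called 0. Fry called 14 in a direction and its mixed test 24. Tested members were selected for variation over these same arrays, so a mixed call for every list says little about any of them.

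Genes around Ppif on chromosome 14 were compared with the rest, because a targeted allele can carry flanking sequence of the strain it was made in. Of 81 tested genes among the 100 protein-coding genes on each side, 38 changed (46.9%), against 43.6% of other tested genes, an odds ratio of 1.14 (95% interval 0.717 to 1.82, Fisher's exact p = 0.574, two-sided). Counting changes of at least 2-fold gave 9 of 81 against 6.01%, with an odds ratio of 1.96 (0.854 to 3.96, Fisher's exact p = 0.0616). Among these neighbours Wnt5a was 6.01-fold lower, and the basement membrane gene Nid2 rose by 2.25 ± 0.08. Rtraf, an RNA transport factor, rose by 2.27 ± 0.07 with its brightest probe, but its other probe gave -0.03 ± 0.11 (adjusted p = 0.894). Nid2 and Rtraf were chosen for mention after their values were seen.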

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

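The filter at the 70th percentile and the wider denominator around Ppif were chosen after the data had been seen; all other settings were planned. Ppif stayed lower and called under every setting run, and its log2 fold change ran from -1.42 to -1.33 when single arrays were left out. Leaving out 1 array gave between 4079 called probes (without knockout C) and 5903 (without wild type C), and 5 called lists each time. Of the 5423 calls, 3981 and 4919 were shared, in the same direction. Median scaling shared 5019 calls and lowered the upward share from 49.0% to 42.3%.

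The number of called lists was 0 with an estimated correlation and 14 with fry. Fry called replication (median 0.16, adjusted p = 0.0456) and mitosis (0.12, adjusted p = 0.0319), which camera did not; its hypothesis differs from that of camera, since it compares no list with other genes. Chemokines lost their call with an estimated correlation (-1.02, adjusted p = 0.498), with the probe of highest variance (-1.02, adjusted p = 0.0596), with median scaling (-1.02, adjusted p = 0.0601), without the intensity trend (-1.02, adjusted p = 0.0529) and above the 70th percentile (-1.34, adjusted p = 0.0914), where 9 members were left; for the rest the cause was not tested. Adjusted p over the arrays left out ran from 0.0213 to 0.0441. For other lists, 8 list and setting pairs gained a call, 4 lost it and 345 stayed on their side of the threshold. For probes of named genes 48 pairs gained a call, 13 lost it and 2410 stayed on their side of the threshold, called or not; no called direction reversed.

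Whether the letters A, B and C pair the arrays could not be decided. The correlations of deviations for same-letter arrays were 0.101, -0.0899 and 0.0753. Those for arrays of different letters ran from -0.209 to 0.15, so same-letter arrays were not more alike. So few correlations, from deviations that depend on each other within a group, cannot exclude a pairing. With the letters as a replicate block 5273 probes were called. A filter at a detection p under 0.01 and the slide as a block were not run, because the deposited intensities come without detection p-values or slides. Near the lower end of the signal, background cannot be separated from expression, so fold changes of dim probes are the least certain.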

Other observations

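Apart from the count of splits of the arrays and the comparison of genes around Ppif, the tests in this part were chosen only after the result was seen, as was the rule for reading the changes of at least 2-fold around Ppif. Genes known as targets of NF-kB, the transcription factor of inflammatory signalling, were mostly lower in knockout cells. Of 22 tested members of a list written after the data were seen, 2 rose, 19 fell and 1 did not pass (median -0.77, camera adjusted p = 4.76e-09, adjusted p = 0.0183 with an estimated correlation). Several members, among them Ccl2, Ccl7 and Mmp3, were known to have fallen when the list was written, so the list is not independent evidence of its direction. Among its 10 members that no earlier list held, 1 rose, 8 fell and 1 did not pass (median -0.56, camera adjusted p = 0.00139, adjusted p = 0.0649 with an estimated correlation), although the fall of Traf1 in this set had been seen too. The inhibitor gene Nfkbia was 1.91-fold lower, the subunit gene Relb 1.73-fold lower and the signalling adaptor gene Traf1 4.04-fold lower, while the prostaglandin synthase gene Ptges rose 2.29-fold.

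The remaining lists were also written after the data were seen, so their tests are not independent evidence of direction either. Set test p-values of all these later lists, NF-kB included, were adjusted over these lists alone. They are not comparable with those of the 24 earlier lists. Genes of retinoid handling went both ways: of 10 tested, 2 rose, 5 fell and 3 did not pass (camera adjusted p = 0.0663). Crabp2 and Crabp1, cellular retinoic acid-binding proteins, moved apart, with Crabp2 4.59-fold lower and Crabp1 3.85-fold higher, and Aldh1a3, which makes retinoic acid, was 4.25-fold lower. Of 10 histone genes, which include the linker histone gene H1f2 and have copies close in sequence, 0 rose, 5 fell and 5 did not pass (camera adjusted p = 0.033, adjusted p = 0.384 with an estimated correlation), led by H2bc4 at 5.77-fold lower. Of 25 axon guidance genes 9 rose, 7 fell and 9 did not pass (camera adjusted p = 0.785), with a median of -0.02 and a mean of 0.02. Of 24 lysosomal genes 7 rose, 6 fell and 11 did not pass (camera adjusted p = 0.701). The cathepsin gene Ctsh rose 3.25-fold and Ctsk was 2.56-fold lower.

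The 6 arrays can be split into 3 and 3 in 10 ways. Only 1 split, the real one, called as many as 5423 probes, and the highest count of any other was 0, but 10 splits are too few for a share under 0.05.

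Ppif kept 38.7% of its wild-type signal in the knockout arrays. Wild-type cells of these cultures mixed into the knockout cultures would leave every gene at least that share, but 81 of 13584 bright probes lay below it by more than 2 standard errors, down to 5.35% for Slco4a1. The tables therefore argue against such a mixture as the source. A transcript that still carries the probed sequence may remain, and a probe outside the deleted part is a candidate explanation, but only 1 named Ppif probe could be compared, so the explanations cannot be told apart. No biological explanation was tested.

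Several widely expressed genes, among them Rbm45, Aqr and Mff, were near the lower end of the signal in wild type and bright in knockout. Sequence variants under the probes in the wild-type cells may account for some of them: a probe of Mcm6 rose by 5.03 where its brighter probe gave 0.20, and 17 genes had such disagreeing probes. In 58.8% of these (10 of 17, exact 95% interval 32.9 to 81.6) the changed probe was higher in knockout, against 52.0% of 152 genes whose probes changed together (Fisher's exact p = 0.62). This count of directions over few genes does not decide it, and it leaves out size. The largest rises among the 17 were those of Mcm6, Tor1aip2 (2.80) and Rtraf (2.27), whereas the largest fall was that of Lpp (-1.19). The difference in size was seen afterwards and was not tested. Ifi202b, known as poorly expressed in C57BL/6 mice, was bright in all wild-type arrays (10.82 ± 0.083) and not in knockout (6.93 ± 0.18), although the labels give that background for both genotypes. Donor-strain sequence flanking the targeted allele would place changes near Ppif. Over all called genes the odds ratio of 1.14 (95% interval 0.717 to 1.82) met the rule fixed in advance for arguing against it. With 50 genes on each side the ratio was 1.15 and its interval reached 2.06. All protein-coding genes as the denominator gave 1.34 (Fisher's exact p = 0.11). Named probes were selected for variation over these arrays, which can flatten such a contrast, so flanking sequence is not excluded. For changes of at least 2-fold the ratio was 1.96 (0.854 to 3.96, Fisher's exact p = 0.0616), and these stay open. There were 9 such genes near Ppif against 452 elsewhere. Variants elsewhere and an effect of the genotype itself stay open and untested.

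Positional and lineage genes set the cultures apart. Of 13 tested Hox genes of paralog groups 1 to 8, 11 rose, 0 fell and 2 did not pass, whereas of 11 genes of groups 9 to 13, 2 rose, 7 fell and 2 did not pass (Fisher's exact p = 0.000464 over genes, which are not independent). Cultures drawn from different body regions, the wild-type cells from a more posterior or distal part, are a hypothesis that these directions prompted, so the test on the same genes cannot support it; it stays open, and arrays of cultures from known regions, which the design does not hold, would be needed to decide it. More of every other cell type in the knockout cultures would raise all lists of their markers, but not all rose. Mean log2 fold changes of the 6 lists moved apart (permutation p = 0.00342 over 28 tested genes, which are not independent). The permutation compared the lists with each other, so its p does not show that any list failed to rise. Cartilage, bone and adipose markers had 1.35 ± 1.11 (SD, n = 7 genes) and neural markers -1.02 ± 1.06 (n = 5 genes). Those directions were seen before the test was chosen, and the leukocyte and skeletal muscle lists held 2 genes each. Other shifts in the mix of cell types are not excluded. An effect of the lost cyclophilin D on the positional and lineage genes stays open, because each genotype comes from its own cultures and the design holds no second set.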
